A study of Homo sapiens with 6 samples.

How the data were processed

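Primary human epidermal keratinocytes from a commercial supplier, the cells that form the outer layer of the skin, were grown in culture wells and given recombinant human LIGHT or phosphate-buffered saline (PBS), per the labels. LIGHT is the TNF superfamily cytokine encoded by TNFSF14. It was given at 100 ng/ml for 48 h, and RNA was taken from 3 replicates per group and sequenced as read pairs on a NovaSeq instrument. The labels describe the replicates as wells cultured in triplicate and do not say that they came from separate donors or separate days. The p-values therefore measure the spread between these 6 samples, which may be technical. Groups were taken from the stimulation label of each sample.

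The deposited table holds raw read counts for 58347 annotated features in 6 libraries, each row naming an Ensembl identifier, a symbol and a feature class. The submitters' processing notes name STAR 2.6.1, Bowtie 1.0.0, HTSeq 0.7.1 and the genome build GRCh38, with no role or order. The library kit, the strand setting of the counting and the annotation release are not given in the sources used here. No row of the table lacked a gene. Total counts per library ranged from 1713735 to 2209772, and 22783 features had at least 1 count.

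Features were placed on the GENCODE release 29 annotation of GRCh38 by Ensembl identifier, which held 58084 of the 58347 features. For each feature, the exonic bases that overlap exons of genes on the other strand were counted. Because the strand setting is not stated, a gene and a partner on the opposite strand cannot be told apart by name alone, and features named below under their own names that have such exons are marked as such.

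The comparison was LIGHT against PBS, 3 libraries each. Features were kept with filterByExpr, which left 7341. Library sizes were scaled by the trimmed mean of M values (TMM). Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with group as the only term. Adjusted p-values are Benjamini-Hochberg values over all features tested, with a threshold of 0.05. CPM values, counts relative to library size, are TMM-scaled, and means are given ± SD with n = 3. The standard error (SE) of a log2 fold change was derived from the fitted coefficient and its F statistic.

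A second reading was chosen after the data were seen, because most counts lay on features opposite abundant genes. Features with at least 50 exonic bases opposite other genes, and at least 90% of those bases opposite 1 protein-coding gene, were tied to that gene. Their counts were summed under its name and fitted in the same way. This covered 5563 features opposite 4721 genes and 68.67% of all counts, and 2766 genes passed the filter. These sums are called opposite-strand counts.

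Before the data were examined, 42 gene lists with 1153 entries were fixed, of which 1151 entries matched a feature. They cover inflammation and NF-κB signalling, the diseases in the series title, epidermal differentiation and junctions, interferon and antigen presentation, growth, metabolism, RNA quality and markers of other cell types. Lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, where at least 5 members were measured. Adjusted p-values for lists are Benjamini-Hochberg values over the lists tested.

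The rule for named genes was also fixed beforehand. It took the 6 largest rises and 6 largest falls among features past the threshold with an average log2 CPM of at least 1, a symbol that is not a clone name and no overlap between the groups. It took the members of each list with the smallest adjusted p past the threshold, up to 3 for the psoriasis, atopic dermatitis, NF-κB target, chemokine and cornified envelope lists and up to 1 for others. TNFRSF14, LTBR, TNFRSF6B, TNFSF14, TSLP, CCL20, CXCL8, S100A7, KRT1, KRT10, FLG and MKI67 were always taken. The same rule was applied to the opposite-strand counts. Some of the genes it took are not reported here. Abundant genes used to describe the strand of the counts, and further list members given as examples, were chosen after their values were seen.

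The tests were run first on simulated counts for the same features and library sizes. As listed, edgeR recovered 82.98% of the features changed by log2 1 and 42.55% of those changed by log2 0.5 over 7341 features, with 0.84% false calls. For opposite-strand counts over 2766 genes, the shares were 85.57% and 61.22%, with 2.72% false calls. On the same simulated counts DESeq2 recovered fewer, 63.83% and 32.98% as listed and 81.44% and 50.00% opposite, with 0% false calls. Voom gave 5.74% false calls as listed and 4.00% opposite. The simulation changed 188 listed features and 195 genes opposite, with no correlation between them. The data gave 1023 and 601 calls, so these shares may not hold for the data. Alternatives were DESeq2 size factors, library size alone, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, voom, robust dispersion, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. XIST and Y-linked genes were left out of all tables of genes.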

Results

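RNA from human epidermal keratinocytes was sequenced after 48 h with recombinant LIGHT at 100 ng/ml or with PBS, in 3 libraries per group. The series title places the comparison in the setting of psoriasis and atopic dermatitis, inflammatory skin diseases in which keratinocytes take part. Total counts were 1713735, 2026818 and 1996080 in the PBS libraries and 1930091, 2209772 and 2009046 in the LIGHT libraries. Pearson correlations of log2 CPM were 0.981 to 0.983 within groups and 0.971 to 0.974 between groups. The first principal component of the 500 most variable features held 54.4% of the variance and separated the groups. Counts of every pair of libraries within a group differed by more than sampling noise, with chi-square per degree of freedom from 1.32 to 1.66, so no library was counted as a duplicate.

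Most counts in the table lay on features whose exons overlap another gene on the opposite strand. Such features made up 21.49% of the table and held 91.69% of the 11885542 counts, and the antisense RNA class alone held 49.79%. GAPDH, a glycolytic enzyme gene expressed in nearly all cells, had 467 counts under its own name in the 6 libraries. AC006064.4, a feature on chromosome 12 from 6537794 to 6538370 whose 422 exonic bases all lie opposite GAPDH exons, had 412943. The translationally controlled tumour protein gene TPT1 had 5549 counts and AL138963.3 opposite to it 410391. The ferritin heavy chain gene FTH1 had 443 counts and BEST1 opposite to it 182279. Of abundant genes without exons opposite them, ACTB had 1670 counts, B2M 257 and the basal keratin gene KRT5 12213. The antisense class held 48.95% to 49.23% in the PBS and 50.31% to 50.49% in the LIGHT libraries. SLC12A5-AS1, 1 feature of that class, rose from a mean of 1323 to 14186 CPM, so this difference need not be a broad rise. In each library, between 91.3% and 91.96% of counts lay on features with opposite exons. Results below are therefore given for features under their own names and for the counts opposite a gene, though not in both readings for every gene. Besides those given with the gene opposite to them, ANO1, CALR, CDSN, CFLAR, CXCL14, FLG, HLA-F, HSP90B1, HYOU1, IL4R, KRT7, KRT10, OVOL1, PDIA6, PLAU, SLC2A1, SSPN, TNFRSF10A and VIM have exons opposite another gene.

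**Figure D1:**
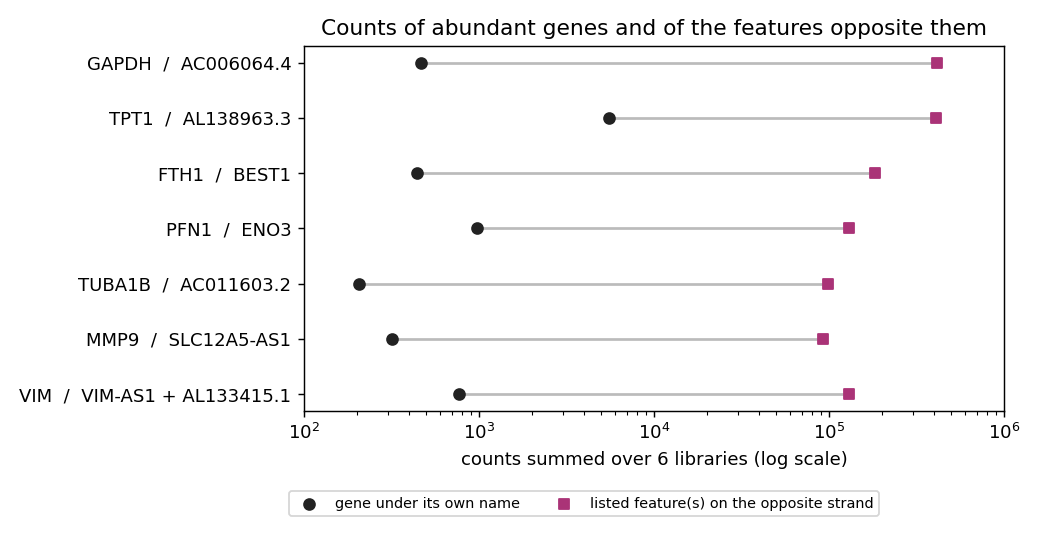
Counts summed over 6 libraries, on a log axis, for 7 abundant or changed genes under their own names (circles) and for the listed features on the opposite strand (squares). GAPDH stands at 467 and the feature opposite to it at 412943.

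With LIGHT, the matrix metalloproteinase gene MMP9 and the feature opposite it, the NF-κB subunit gene NFKB2 and the counts opposite vimentin (VIM) and the class I gene HLA-F rose. The immediate-early gene EGR1, the chemokine gene CXCL14, the cyclooxygenase gene PTGS2 and the keratin genes KRT5, KRT14 and KRT17 fell. Among listed features, 543 rose and 480 fell at adjusted p < 0.05 of 7341 tested, and 87 and 69 of these changed by log2 1 or more. The groups did not overlap for 968 of the 1023 calls. Over all tested features 26.9% had no overlap, where chance gives 10%. Scaling by library size alone moved the split to 420 higher and 636 lower. Of the features that rose 466 had exons opposite another gene and 77 had none, and of those that fell 377 and 103. Opposite-strand counts rose for 300 genes and fell for 301 of 2766, with 28 and 31 at log2 1 or more. Of 205 genes that rose opposite and were tested under their own names, 45 rose there, 8 fell and 152 did not pass, and of 192 that fell opposite 20 fell, 14 rose and 158 did not pass. DESeq2 called fewer listed features, 306 higher and 255 lower.

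MMP9 and SLC12A5-AS1, which overlap on chromosome 20, were among the 6 largest rises of listed features under the rule for named genes. They had 320 and 92009 counts in the 6 libraries. SLC12A5-AS1 (46013500 to 46022073), which has 430 exonic bases opposite MMP9, rose from 1323 ± 57.5 to 14186 ± 320 CPM (SD, n = 3), a log2 fold change of 3.42 ± 0.04 (SE, adjusted p = 1.9e-65). MMP9 (ENSG00000100985, 46008908 to 46016561) rose from 4.52 ± 0.84 to 49.3 ± 3.6 CPM under its own name, with a log2 fold change of 3.43. The other largest rises among listed features were DNAH17-AS1 (3.93, opposite the axonemal dynein gene DNAH17), PLA2G4C-AS1 (2.75, opposite the phospholipase gene PLA2G4C), the sarcospan gene SSPN (2.598) and the chloride channel gene ANO1 (2.12). PBS means of DNAH17-AS1 and SSPN were 0.72 and 1.31 CPM, so their folds rest on few counts, and SSPN was at 3.80 without PBS replicate 1. ANO1 and PLA2G4C-AS1 also held few counts, 62 and 122 in the 6 libraries. Opposite-strand counts rose most for the cardiac and smooth muscle coactivator gene MYOCD (4.77), the GATA factor gene GATA6 (3.37), DNAH17 (3.23), NCALD (2.76), PLA2G4C (2.74) and the steroid dehydrogenase gene HSD17B2 (2.47). DNAH17 was at 2.63 without PBS replicate 2, 4.33 without PBS replicate 3 and 3.93 with features tied by at least 200 bases to 1 gene alone, and under its own name at 0.11 (adjusted p = 0.65). The counts opposite HSD17B2 rose from 58.5 ± 8.8 to 324 ± 20 CPM, whereas those opposite MYOCD started at 1.80 and those opposite GATA6 at 1.04 CPM. The counts opposite PLA2G4C are those of PLA2G4C-AS1 given above. Those opposite DNAH17 are the counts of DNAH17-AS1 and of the feature PGS1.

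The largest falls among listed features were CXCL14 (log2 fold change -2.51), a chemokine made by resting epithelia, and EGR1 (-2.21), an immediate-early transcription factor gene. NCBP2L (-2.16, opposite TSC22D3), TMEM51-AS1 (-2.01, opposite KAZN), LINC01343 (-1.95) and FLNC-AS1 (-1.91, opposite the filamin gene FLNC) followed. CXCL14 went from 66.8 ± 10.0 to 11.99 ± 5.5 CPM and EGR1 from 33.7 ± 4.8 to 7.17 ± 2.06 CPM. Opposite-strand counts fell most for the glucocorticoid-induced gene TSC22D3 (-2.17), the hexokinase-like gene HKDC1 (-2.16), the growth factor binding protein gene IGFBP5 (-2.14), KAZN (-2.02), FLNC (-1.92) and KRT10 (-1.72, counts on the coding gene TMEM99). KAZN under its own name rose by 0.41. The counts opposite TSC22D3, KAZN and FLNC are those of NCBP2L, TMEM51-AS1 and FLNC-AS1 given above. The ties of TSC22D3 and FLNC rest on 71 and 68 bases. LINC01343, TMEM51-AS1 and NCBP2L held 67, 79 and 102 counts in the 6 libraries and the feature opposite HKDC1 75. Their folds rest on few counts.

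**Figure D2:**
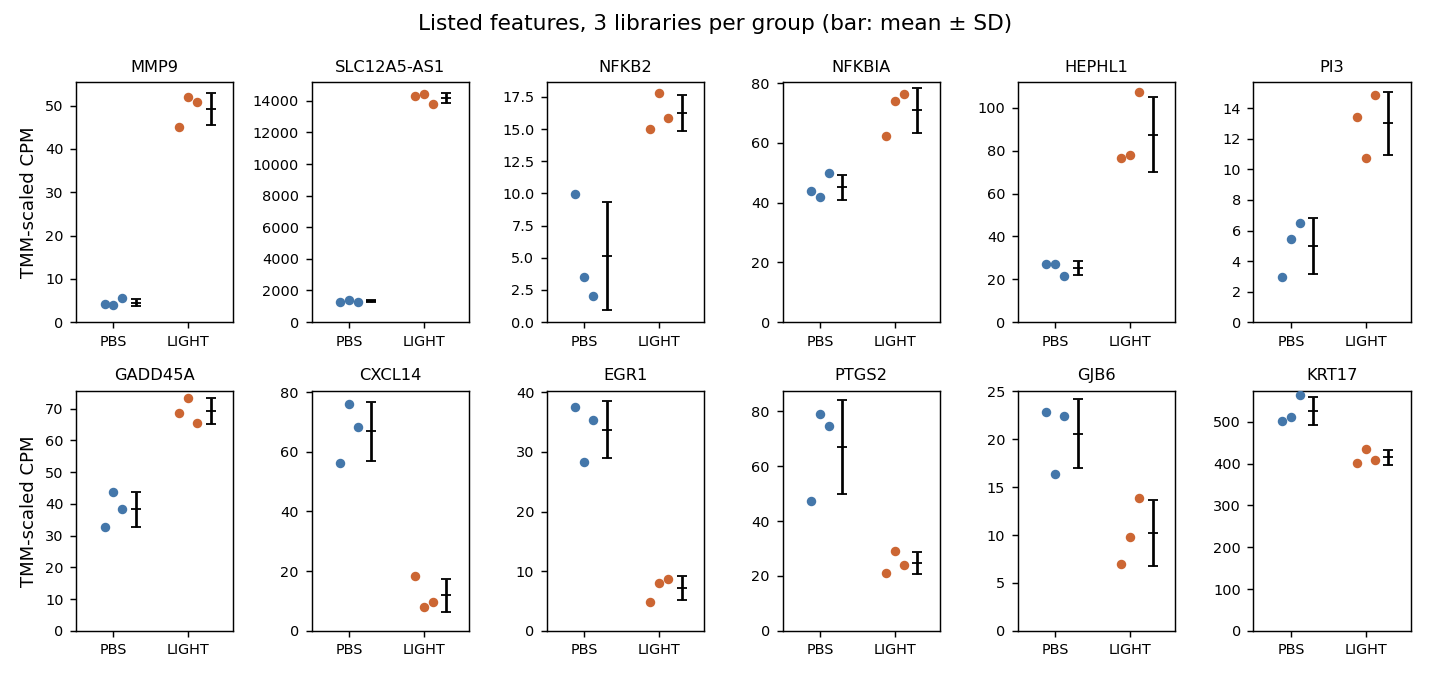
TMM-scaled CPM of 12 listed features in each library, with PBS in blue and LIGHT in orange; each axis starts at 0 and bars give mean ± SD of 3 libraries. MMP9 rose from a mean of 4.52 to 49.3 CPM and EGR1 fell from 33.7 to 7.17 CPM.

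Targets of NF-κB, the transcription factor family that LIGHT receptors are known to activate, rose under their own names for 5 of 13 measured members and fell for 1, with the same counts adjusted over the list alone. NFKB2, which encodes the p100 subunit of the noncanonical pathway, rose from 5.14 ± 4.23 to 16.2 ± 1.4 CPM (log2 fold change 1.72, adjusted p = 2.8e-05, and 2.55 without PBS replicate 1). NFKBIA, the inhibitor that NF-κB itself induces, rose from 45.2 ± 4.2 to 70.9 ± 7.5 CPM (0.65), and the urokinase gene PLAU by 0.75. DESeq2 called 3 of the 13 higher and 0 lower. The list moved up in the camera test (adjusted p = 0.013), with adjusted p = 0.34 with an estimated correlation. The noncanonical NF-κB pathway list had 2 of 5 members higher, or 3 adjusted over the list alone (camera adjusted p = 0.04998, and adjusted p = 0.34 with an estimated correlation). Without LIGHT replicate 2, the adjusted p of these lists was 0.061 and 0.059, and that of the noncanonical list was 0.071 without PBS replicate 2. Over all alternatives it ranged from 0.0008 to 0.36 for the targets and from 0.014 to 0.37 for the noncanonical pathway. Among opposite-strand counts of NF-κB targets, the caspase-8 regulator gene CFLAR (0.56) and PLAU (0.26, counts on the coding gene C10orf55) rose, IER3 fell (-0.63), and 3 of 7 members rose and 1 fell, also adjusted over the list alone, with camera adjusted p = 0.42.

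Of the psoriasis epidermis list, 3 of 7 measured members rose and 2 fell under their own names, also adjusted over the list alone. Those that rose were HEPHL1, a copper-dependent ferroxidase gene (log2 fold change 1.80, 25.2 ± 3.3 to 87.5 ± 17.4 CPM), the RNase gene ZC3H12A (1.501) and the elastase inhibitor gene PI3 (1.35). The gap junction gene GJB6 fell from 20.5 ± 3.6 to 10.2 ± 3.4 CPM (-0.99). The list as a whole did not pass camera (adjusted p = 0.17). Of the atopic dermatitis list, 1 of 6 members changed, also adjusted over the list alone: PTGS2, the inducible cyclooxygenase gene, fell from 67.1 ± 17.2 to 24.7 ± 4.1 CPM (camera adjusted p = 0.54). Opposite-strand counts of that list's genes rose for the interleukin-4 receptor gene IL4R (0.32) and fell for the cytokine signalling inhibitor gene CISH (-0.69), and these were also the counts adjusted over the list alone for its 3 measured members. IL4R under its own name was at -0.25 (adjusted p = 0.73). The CISH call was lost with DESeq2 (adjusted p = 0.089) and without PBS replicate 1 (0.13), LIGHT replicate 1 (0.06) or LIGHT replicate 2 (0.093), and its counts lie on the coding gene MAPKAPK3. The only psoriasis member with opposite-strand counts did not pass over all genes and rose adjusted over the list alone. Of the chemokine list, CXCL14 fell and the 1 other measured member did not pass over all genes; adjusted over the list alone it rose. Of the 5 measured inflammatory cytokine members, 0 passed with edgeR under either adjustment, 1 had an unadjusted p under 0.05, and 0 passed with DESeq2 or voom.

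Several genes of the question did not pass the low-count filter under their own names and were not tested in the main fit. CCL20, S100A7 and TNFRSF6B had 0 counts in the 6 libraries, TNFSF14 had 1, TSLP 2, CXCL8 3, TNFRSF14 9, KRT1 27 and MKI67 54. The MKI67 counts were 21 in the PBS and 33 in the LIGHT libraries. Few counts under these names do not show low expression, since GAPDH itself had 467 under its own name. Of these genes only TNFRSF14 had a tied feature on the opposite strand. Of the LIGHT receptors, LTBR went from 20.01 ± 6.9 to 28.9 ± 2.8 CPM (log2 fold change 0.51, adjusted p = 0.071) and lies opposite SCNN1A exons. Without PBS replicate 3 its adjusted p was 0.0046, and over all alternatives it ranged from that value to 0.3. The feature opposite the other receptor gene, TNFRSF14, rose from 70.3 ± 1.3 to 111 ± 8 CPM (0.66, adjusted p = 2.5e-05). The receptor and ligand list had 1 measured member under its own name, LTBR, which passed adjusted over the list alone, and 2 opposite, of which 1 rose under either adjustment. The TNF receptor superfamily had 0 of 7 past the threshold under own names with either adjustment in edgeR and 0 with DESeq2 or voom, with 2 at an unadjusted p under 0.05. It had 3 of 4 higher opposite, TNFRSF10A among them (0.52, and -0.65 under its own name with adjusted p = 0.2), where 3 rose and 1 fell adjusted over the list alone.

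Genes of the extracellular matrix and its remodelling rose for 12 of 33 measured members and fell for 2 under their own names, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.00066, and adjusted p = 0.34 with an estimated correlation). The laminin genes LAMA3 (0.94) and LAMB3 (0.71), fibronectin (FN1, 0.47) and the activin gene INHBA (1.20) rose. Opposite-strand counts rose for 3 of 9 members and fell for 2, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.13, and 0.049 without PBS replicate 3), with integrin αv (ITGAV) at 0.89. MMP9 was not among these 9 members, since SLC12A5-AS1 was not tied to it. In the TGF-β and epithelial-mesenchymal transition list, the opposite-strand counts rose for 4 of 7 members and fell for 1, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.0066, and adjusted p = 0.12 with an estimated correlation). The counts opposite the intermediate filament gene VIM rose from 9820 ± 776 to 22022 ± 1047 CPM (1.17), and VIM under its own name rose by 1.23. Under own names 4 of 17 members of that list rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.087, and 0.041 without LIGHT replicate 1). Counts opposite KRT7, a keratin of simple epithelia, rose from 1567 ± 176 to 3257 ± 156 CPM (1.06), 1 of 3 members of the simple epithelial, gland and Merkel cell list opposite under either adjustment. KRT7 was also the 1 of 4 that rose under its own name (0.68, under either adjustment), a call lost with DESeq2 (adjusted p = 0.21), library size alone (0.053) and no low-count filter (0.063), without PBS replicate 2 or 3 (0.083 and 0.31) and without LIGHT replicate 2 or 3 (0.073 and 0.22).

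Among cornified envelope and differentiation genes, opposite-strand counts fell for 6 of 9 measured members and rose for none, with the same counts adjusted over the list alone (camera adjusted p = 5.8e-06, and adjusted p = 0.23 with an estimated correlation). The calmodulin-like gene CALML3 fell from 395 ± 26 to 198 ± 15 CPM (-1.001), the transcription factor gene OVOL1 by 0.35 and LY6D by 0.33 on the log2 scale. OVOL1 under its own name was at 0.38 (adjusted p = 0.65). Counts opposite KRT10, a keratin of suprabasal cells, fell from 48.5 ± 22.0 to 14.95 ± 4.2 CPM over 56 bases shared with TMEM99, which holds them, whereas KRT10 under its own name went from 19.3 ± 4.8 to 16.8 ± 5.0 CPM (adjusted p = 0.64). Under own names 3 of 19 members rose and 3 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.83), and DESeq2 called 0 in either direction, with 6 at an unadjusted p under 0.05. SPRR1A rose (1.705), as did CDSN (0.45), a call lost with DESeq2 (adjusted p = 0.051), and the transcription factor gene MAF (-1.03) and filaggrin (FLG, -0.26) fell. SPRR1A lost its call without LIGHT replicate 2 (adjusted p = 0.13), MAF without PBS replicate 3 (0.17) and with DESeq2 (0.078). Over all alternatives the adjusted p ranged from 0.003 to 0.13 for SPRR1A and from 0.0033 to 0.17 for MAF. FLG lost its call with DESeq2 (0.17), voom and the unfiltered features, and when any library but LIGHT replicate 1 was left out (0.0503 to 0.21). Counts opposite FLG went from 64.3 ± 32.7 to 52.4 ± 6.6 CPM (adjusted p = 0.29, and 0.0053 without PBS replicate 1, with the log2 fold change then at -0.61). In the listed cornified envelope list the median log2 fold change was -0.12 and the mean 0.02.

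KRT17 fell from 526 ± 34 to 415 ± 19 CPM (-0.34), and 3 of 4 stress keratin members fell, also adjusted over the list alone, with KRT6B at 0.29 (adjusted p = 0.29). The basal keratinocyte list had 5 of 21 members higher and 3 lower, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.17). The basal keratins KRT5 (-0.60) and KRT14 (-0.42) were among those lower. Opposite-strand counts of the list rose for 3 of 6 members, led by the stem cell marker gene LRIG1 (1.47, counts on the coding gene SLC25A26, and -0.02 under its own name with adjusted p = 0.97), and fell for 1, also adjusted over the list alone (camera adjusted p = 0.0066, and adjusted p = 0.12 with an estimated correlation). The junction list had 1 of 23 members higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.25). DESeq2 called 0 of these higher and 1 lower. Counts opposite E-cadherin (CDH1) fell from 1812 ± 23 to 1403 ± 58 CPM (-0.37), the only one of 2 measured members past the threshold over all genes, with 2 lower adjusted over the list alone.

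Class I antigen presentation genes rose for 7 of 8 members in opposite-strand counts, also adjusted over the list alone (camera adjusted p = 7.2e-13, and adjusted p = 0.056 with an estimated correlation). Counts opposite HLA-F rose from 241 ± 2 to 575 ± 20 CPM (1.25), and those opposite HLA-B by 0.70. HLA-F under its own name was at -0.07 (adjusted p = 0.77). HLA genes are close paralogs whose reads the counting could have divided. Counts opposite the chaperone gene CALR rose from 1614 ± 43 to 2781 ± 131 CPM (0.79), and CALR under its own name by 0.84. Under own names 4 of 12 members of the list rose and 0 fell, or 5 adjusted over the list alone (camera adjusted p = 0.079, and 0.041 without LIGHT replicate 1), and DESeq2 called 1. Unfolded protein response genes rose for 4 of 4 members opposite and for 4 of 16 under their own names, with none lower, HSP90B1 among them (0.70). Adjusted over the list alone these were 4 opposite, and 5 higher and 1 lower under own names (camera adjusted p = 0.17). Of interferon-stimulated genes 3 of 5 rose and 1 fell opposite, also adjusted over the list alone (camera adjusted p = 0.053, with 0.048 without PBS replicate 3 and 0.031 without LIGHT replicate 3). XAF1, a proapoptotic interferon target gene, rose by 1.01. Under own names 1 of 11 rose under either adjustment (camera adjusted p = 0.17), PARP9 (0.37, opposite DTX3L). That call was lost with DESeq2 (0.15), with library size alone (0.053), without PBS replicate 2 or 3 (0.091 and 0.19) and without LIGHT replicate 1 or 2 (0.081 and 0.16). TYMP of the interferon-γ list rose from 4.88 ± 2.01 to 16.8 ± 3.2 CPM (1.76), 1 of 3 members under either adjustment.

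**Figure D3:**
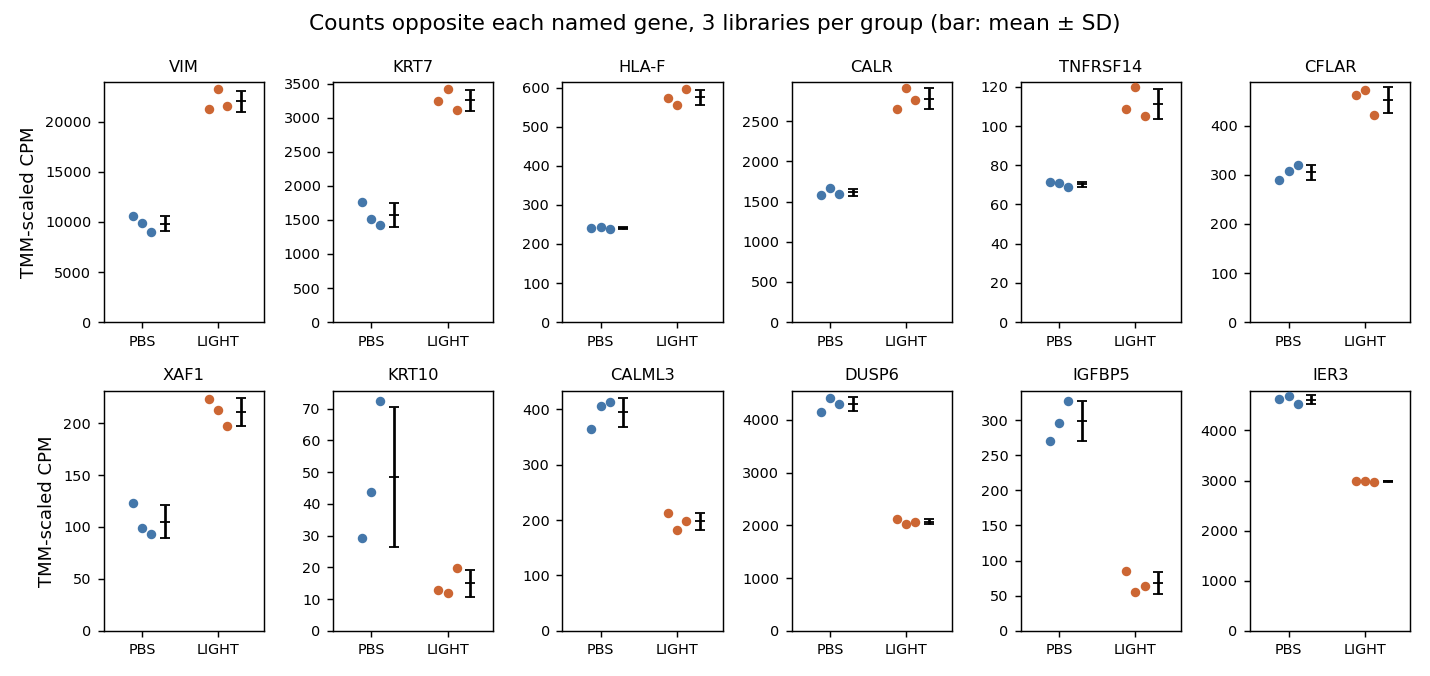
TMM-scaled CPM of the counts opposite 12 named genes in each library, with PBS in blue and LIGHT in orange; each axis starts at 0 and bars give mean ± SD of 3 libraries. VIM rose from a mean of 9820 to 22022 CPM and DUSP6 fell from 4291 to 2068 CPM.

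The list of immediate-early and dissociation stress genes holds genes that respond within minutes to growth factor or handling signals. Under own names 7 of 17 members fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.34 with an estimated correlation). EGR1, MYC (-1.13), JUN (-0.81) and the heat-shock gene HSPB1 (-0.47) were among them, and DESeq2 called 3 lower. Opposite-strand counts fell for 5 of 6 members and rose for 0, also adjusted over the list alone (camera adjusted p = 3.0e-10, and adjusted p = 0.056 with an estimated correlation). Counts opposite the ERK phosphatase gene DUSP6 fell from 4291 ± 133 to 2068 ± 44 CPM (-1.05, adjusted p = 5.8e-22), and those opposite JUNB by 0.69 and NR4A1 by 1.54 on the log2 scale. The counts opposite JUNB lie on the coding gene HOOK2, and JUNB under its own name was at -0.37 (adjusted p = 0.16). EGFR ligands and growth factors fell for 3 of 11 members under own names, or 4 adjusted over the list alone, with none higher (camera adjusted p = 0.069, with 0.046 without PBS replicate 2 and 0.033 without PBS replicate 3). The amphiregulin gene AREG fell from 286 ± 7 to 188 ± 29 CPM (-0.60) and counts opposite VEGFA fell by 0.48 on the log2 scale. Of the 3 members measured opposite, 1 rose and 1 fell under either adjustment.

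Ribosomal protein genes fell for 4 of 11 members opposite and rose for 0, also adjusted over the list alone (camera adjusted p = 0.0058, and adjusted p = 0.12 with an estimated correlation), RPS3A from 3023 ± 58 to 2581 ± 11 CPM (-0.23, counts on the coding gene SH3D19). Under own names 2 of 51 fell, or 1 adjusted over the list alone (camera adjusted p = 0.097), with RPL8 at -0.71 and adjusted p = 0.062 without LIGHT replicate 2. NRF2 and oxidative stress genes fell for 4 of 7 opposite with none higher, also adjusted over the list alone (camera adjusted p = 0.0018, and adjusted p = 0.13 with an estimated correlation). Under own names 2 of 13 fell under either adjustment and 0 with DESeq2, which had 2 at an unadjusted p under 0.05 (camera adjusted p = 0.66, median log2 fold change 0.04, mean -0.07), among them the pentose phosphate enzyme gene TKT (-0.60). The TKT call was lost with DESeq2 (adjusted p = 0.066) and without LIGHT replicate 3 (0.054). Mitochondrially encoded genes fell for 5 of 13 members, or 6 adjusted over the list alone (camera adjusted p = 0.0038, and adjusted p = 0.36 with an estimated correlation), MT-ND5 from 4344 ± 175 to 3750 ± 161 CPM (-0.21), and DESeq2 called 2 lower. Without LIGHT replicate 2 that adjusted p was 0.069, and over all alternatives it ranged from 0.00051 to 0.36. MT-ND6, on the minus strand, held 116398 counts in the 6 libraries, against 47092 for MT-ND5 and 6632 for MT-CO1 on the plus strand. No member of this list was measured in opposite-strand counts, and the strand setting is not stated. A fall of the mitochondrial mRNAs is therefore not shown. Glycolysis and hypoxia genes fell for 3 of 24 under own names, or 2 adjusted over the list alone (camera adjusted p = 0.14), the glucose transporter gene SLC2A1 by 0.94 on the log2 scale. Opposite, 1 of 7 rose and 3 fell under either adjustment (camera adjusted p = 0.073, and 0.031 without PBS replicate 3), with GAPDH at -0.22. RPS3A, MT-ND5 and SLC2A1 fell under TMM, DESeq2 size factors and library size alone. Library size alone moved the median log2 fold change of all listed features by -0.046 and DESeq2 size factors by -0.005. Opposite, these shifts were -0.028 and -0.00051. All are downward, so these settings could hardly have removed a fall. Of oxidative phosphorylation genes 1 of 7 fell opposite under either adjustment (camera adjusted p = 0.62), NDUFS7 (-0.15). That call was lost with DESeq2 (0.084), without PBS replicate 2 or 3 (0.075 and 0.085) and without LIGHT replicate 1 or 2 (0.1 and 0.11). Of 14 under own names, 0 passed (camera adjusted p = 0.69).

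Replication genes rose for 4 of 9 members opposite, also adjusted over the list alone (camera adjusted p = 0.053, with 0.037 without PBS replicate 2, 0.017 without LIGHT replicate 1 and 0.047 without LIGHT replicate 3). DESeq2 called 0 of these 9, with 4 at an unadjusted p under 0.05. The DNA ligase gene LIG1 was at 0.31, a call lost with DESeq2 (0.065) and without PBS replicate 1 (0.052), PBS replicate 3 (0.095) or LIGHT replicate 2 (0.082). Under own names 1 of 10 rose under either adjustment (camera adjusted p = 0.66), RFC5 (0.40, opposite WSB2), a call lost with DESeq2 (0.076) and without PBS replicate 3 (0.083). Of mitosis genes 1 of 7 rose, the cytokinesis gene ANLN (0.35, on the coding gene KIAA0895), and 1 fell opposite under either adjustment (camera adjusted p = 0.42), and 0 of 10 passed under own names (camera adjusted p = 0.92). The list of CDK inhibitors and p53 targets had 2 of 11 higher, GADD45A from 38.3 ± 5.5 to 69.3 ± 4.0 CPM (0.85) among them (camera adjusted p = 0.66). Opposite, 1 of its 5 members rose and 1 fell, MDM2 at -0.45 (camera adjusted p = 0.69), with the same counts in both readings adjusted over the list alone. Apoptosis genes rose for 2 of 6 and fell for 1 opposite, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.31), with CFLAR at 0.56. Under own names 1 of 13 rose, CFLAR (0.67), or 0 adjusted over the list alone (camera adjusted p = 0.83). That own-name CFLAR call was lost with DESeq2 (adjusted p = 0.23), voom (0.076), library size alone (0.062) and no low-count filter (0.1), and when any library but LIGHT replicate 1 was left out (0.076 to 0.22).

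Lipid and eicosanoid enzyme genes moved in both directions. Opposite ALOX12B, a lipoxygenase gene of the skin barrier, counts rose from 102 ± 21 to 154 ± 9 CPM (0.59), 1 of 4 barrier lipid members under either adjustment. The water and glycerol channel gene AQP3 was the 1 of 9 barrier members that fell under its own name, under either adjustment (-0.58, camera adjusted p = 0.54). That call was lost with DESeq2 (adjusted p = 0.14) and without PBS replicate 2 or 3 (0.065 and 0.14) or LIGHT replicate 3 (0.18). Eicosanoid enzymes had 2 of 4 higher and 1 lower opposite and PTGS2 lower as 1 of 4 under own names, each under either adjustment. Cholesterol synthesis genes had 2 of 7 higher and 1 lower opposite, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.69), with ACAT2 at 0.23 on counts of the coding gene TCP1. Under own names 0 of 18 passed with edgeR, DESeq2 or voom, and 3 had an unadjusted p under 0.05 with edgeR (camera adjusted p = 0.92).

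The only measured antimicrobial peptide gene was PI3, which rose under either adjustment. Of class II genes HLA-DMA was 1 of 2 that rose under its own name under either adjustment (0.68, opposite BRD2), a call lost with DESeq2 (0.099), and 0 of 2 passed opposite. Markers of other cell types had few measured members. Of melanocyte markers 1 of 3 rose, or 2 adjusted over the list alone, PMEL by 0.25, whose exons lie opposite CDK2. That call was lost with DESeq2 (0.059) and without PBS replicate 3 (0.052) or LIGHT replicate 2 (0.05025). The 1 endothelial marker with opposite-strand counts, ROBO4, rose from 6.61 ± 4.18 to 37.5 ± 7.9 CPM (2.46), under either adjustment, and 0 endothelial markers were measured under their own names. Fibroblast markers had 0 of 1 past the threshold under own names and 0 of 2 opposite, and immune cell markers 0 of 1. Complement genes had 0 of 4 past it, innate sensors 0 of 6 (camera adjusted p = 0.92) and 0 of 2 opposite, and interferon-γ genes 0 of 1 and stress keratins 0 of 1 opposite. In all, 10 lists with 67 measured members had 0 past the threshold under own names with edgeR, DESeq2 or voom, and 9 members had an unadjusted p under 0.05 with edgeR. Opposite these were 6 lists with 9 members, of which 1 had an unadjusted p under 0.05. Histone genes were measured in neither reading, and 9 lists had no measured member opposite, chemokines, inflammatory cytokines, the noncanonical NF-κB pathway, complement, antimicrobial peptides, mitochondrially encoded, melanocyte and immune cell lists among them.

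**Figure D4:**
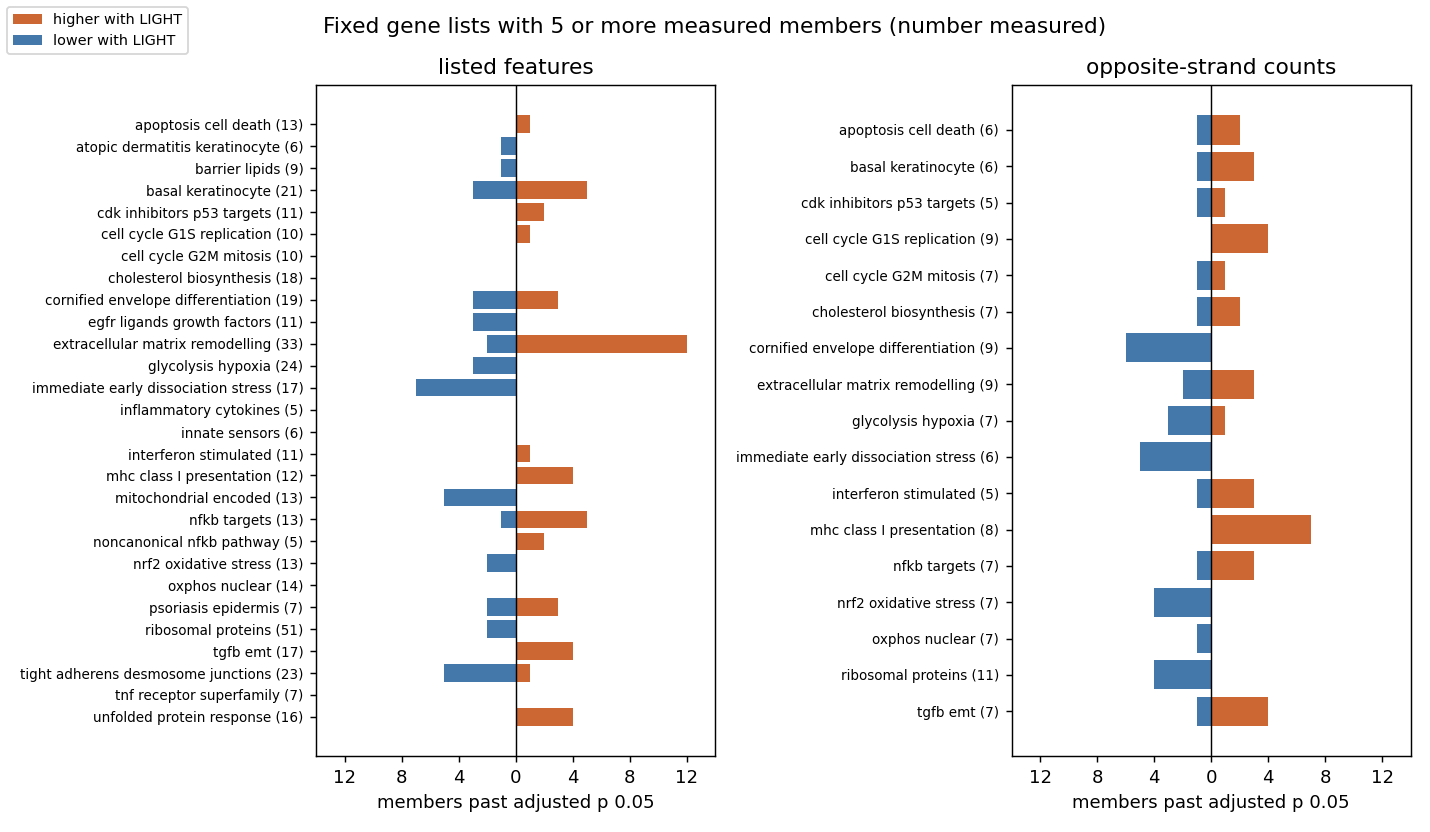
Number of members past adjusted p 0.05 in each fixed gene list with 5 or more measured members, higher with LIGHT to the right and lower to the left, for listed features (left panel) and opposite-strand counts (right panel); the number measured is in parentheses. The longest bars are 12 members higher in the extracellular matrix remodelling list and 7 members higher in the class I presentation list.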

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

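The opposite-strand reading and its stricter tie were chosen after the data were seen; the other settings were planned. Counts of calls stayed within 1.5 times of those reported under DESeq2 size factors, library size alone, no low-count filter, the filter of 5 CPM, voom and robust dispersion; the 5 CPM filter left the listed features as they were. DESeq2 called 306 listed features higher, 255 lower and 43 lower by log2 1 or more, 188 genes lower opposite and 18 by log2 1 or more, and 25 listed genes of the fixed lists higher and 18 lower; it gave 1281 listed features no adjusted p. The opposite-strand reading gave 300 higher, 301 lower, 28 and 31 by log2 1 or more, with fewer genes tested, and the stricter tie 15 lower by log2 1 or more among 1895. The cause of the other differences was not tested.

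Leaving out 1 library gave 423 to 502 listed features higher and 361 to 443 lower, and 251 to 283 and 238 to 278 opposite. Listed genes of the fixed lists numbered 31 to 42 higher and 25 to 36 lower, with 25 lower without PBS replicate 3 and 27 without LIGHT replicate 3. Lists past the set test numbered 2 to 7 of the listed 5, with 2 without LIGHT replicate 2, and 7 to 10 of the opposite 7. With an estimated correlation 0 lists passed in either reading, and with fry, which compares no list with other genes, 11 listed and 14 opposite. Of 43 named listed calls 30 were kept throughout and of 41 opposite 38, and 0 reversed.

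Whether the replicate numbers pair the samples is not settled. Correlations of deviations between same-numbered libraries were 0.1, 0.0274 and 0.0922. Replicates 1 and 3 of each group were closest to their same-numbered library, whereas PBS replicate 2 was closest to LIGHT replicate 3 at 0.0703. LIGHT replicate 2 was closest to PBS replicate 1 at 0.0387. The main fit has no term for pairing, which is not excluded. With the replicate block 594 listed features were higher and 537 lower, 320 and 331 opposite, and 1 listed and 9 opposite lists passed. The listed one was extracellular matrix remodelling (camera adjusted p = 0.016). Immediate-early and mitochondrially encoded genes were then at 0.083, NF-κB targets at 0.36 and the noncanonical pathway at 0.37. Glycolysis and interferon-stimulated lists passed opposite (0.039 and 0.042), and LTBR passed under its own name (edgeR adjusted p = 0.043). Few counts limit low features: the median tested feature had 224 counts in the 6 libraries as listed and 646 opposite.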

Other observations

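Of the tests below, only the correlation of own and opposite-strand changes and the list of ERK output genes were set before their result was seen; the others were chosen after the pattern was seen.

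Of the unfolded protein response list, 4 of 16 members rose under their own names (camera adjusted p = 0.17), among them the endoplasmic reticulum chaperone gene HSPA5 by 0.82 and PDIA6, a disulfide isomerase gene, by 0.72. Opposite-strand counts rose for HYOU1 by 0.39 and PDIA6 by 0.39 (counts on the coding gene ATP6V1C2), whereas HYOU1 under its own name was at 0.14 (adjusted p = 0.87). These members were chosen after their values were seen.

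Most counts lay opposite abundant genes. A library that does not mark strand would give like counts on both strands. The median ratio of opposite to own counts per base was 126 over 25 ribosomal, respiratory and glycolytic genes, with quartiles of 4.48 and 1620. That ratio is biased upward and cannot decide alone. It divides all counts of a tied feature by its overlapping bases, and only genes whose opposite-strand counts passed the filter entered. AC006064.4, whose 422 exonic bases all lie opposite GAPDH exons, had 412943 counts against 467 for GAPDH. For that gene the counts argue against such a library. Antisense transcription beside fully counted mRNA is argued against too, since 56 ribosomal protein genes held 0.212% of counts under their own names and the features opposite 11 of them held 1.55%. A candidate explanation is counting on the strand opposite the transcripts, with a residue under their own names, for which a correlation of at least 0.3 had been set; across 1566 genes, which are not independent replicates, Pearson r was 0.23 and Spearman rho 0.205 (permutation p = 1e-05, the smallest that 100000 permutations can give), and the largest r among re-pairings was 0.106, so neither bound was met. Of abundant genes without exons opposite them, ACTB held 1670 counts, B2M 257 and the ribosomal protein gene RPLP0 214, whereas KRT5 held 12213. Own-name counts can therefore not be read as the mRNA level of ACTB, B2M or RPLP0. Counting on the opposite strand stays open as the cause, because the kit and the strand setting are not given in the sources used here. The own counts of genes with a partner can also hold those of the partner.

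Of class I presentation genes, 7 of 8 rose in opposite-strand counts, with adjusted p = 0.056 for the list with an estimated correlation. A rise of 1 HLA gene shared among its paralogs as the whole change is argued against by 3 of 4 members that are not HLA genes (CALR, ERAP1 and PDIA3) rising as well. Whether the rises of the 4 HLA members are separate cannot be told from these genes. That at least 3 of the other members rose follows from the 7 of 8 and is not a separate test. CALR is also a member of the unfolded protein response list, so the same counts enter both results. An interferon response may contribute: the interferon-stimulated genes had a median log2 fold change of 0.208, under that of the class I list (0.68), and went both ways, with XAF1 at 1.01 and SP110 at -0.61, so the test leaves it open. A direct effect of LIGHT on these genes is also open and was not tested.

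Of immediate-early and dissociation stress genes, 7 of 17 fell under their own names and 5 of 6 in opposite-strand counts, with adjusted p = 0.34 and 0.056 for the list with an estimated correlation. Less heat or handling stress in the LIGHT wells stays open: heat-shock genes had a median log2 fold change of 0.0196 over 6 measured members, but 3 of these belong to the list to be explained, HSPB1 of that list fell (-0.47), and such genes do not measure handling. Lower output of the ERK pathway is a candidate explanation: its output genes outside the fixed list had a median of -0.413 over 4 measured of 10 (SD 0.31), at percentile 0.92 of 10000 random lists of like expression, but only PHLDA1 (-0.28) and EPHA2 (-0.67) passed. Each gene was taken in the reading with more counts, PHLDA1 and ETV4 (0.03, adjusted p = 0.88) opposite and EPHA2 and SPRED2 (-0.55 on 53 counts, adjusted p = 0.52) under their own names, so the median rests on both readings. ERK activity itself was not measured, and 4 genes are few.

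The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1023 listed calls and 601 opposite, and the highest of the other splits gave 0 in both readings. Only 1 split, the real one, gave as many. Every other split mixes LIGHT and PBS libraries, so the difference between the groups enters the spread and makes calls unlikely from the outset. No conclusion is drawn from the 0 calls.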
